A study of Mus musculus with 17 samples.

How the data were processed

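The data are bulk RNA sequencing of sorted mouse lung macrophages in 17 libraries of 6 groups. Groups and replicate names were taken from the sample labels. The deposited sea level columns carry only letters (E and F for alveolar, A, B and C for interstitial cells), which were used as names of columns and pair nothing. Per the labels' protocols, libraries were made with the Nugen Ovation kit, which amplifies the RNA.

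The authors deposited 4 tables, each comparing 1 exposed group with sea level. Per the submitters' processing notes, expression was computed with Cufflinks on mm10. The aligner, its settings, the annotation and the versions are not given in the sources used here. The library columns hold FPKM as deposited by the authors. Per the file headers, each table also holds the authors' group means in FPKM, a signed linear fold of those means, a p-value and a q-value, whose test is not given in the sources used here. A q-value of 99 in the deposited tables was read as marking genes that the authors did not carry into their adjustment, which no source used here states. The cell value 999999999 was read as missing, because the authors' means leave it out. The table for interstitial cells at day 14 is named for the alveolar sea level group but its columns are those of interstitial cells at sea level. The sea level columns were identical in the tables that share them, in 43611 of 43611 lines each, so that the groups of a cell type could be fitted together. Columns that name no sample of the series numbered 0.

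Each table has 43611 lines with 43548 gene identifiers. The 63 second lines of an identifier were added to the first. Of the identifiers, 42384 are in GENCODE release M21 for GRCm38 (mm10), from which biotypes, coordinates, transcript lengths and selenocysteine features were taken. For a symbol with more than 1 identifier, the one with the highest mean was used. The share of the 31-base words of a gene's transcripts that also occur in another gene or pseudogene was computed from that annotation, and genes with shared words are reported as uncertain, because the way Cufflinks split such reads here is not given.

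Depth is not in the tables. For 4436 genes with 1 annotated transcript of at least 1500 bases, the smallest step between values, with 150 bases taken off the length, gave an approximate number of fragments per library, which served only as a description. Low values rest on few fragments, so small differences at low FPKM were not detectable at this depth.

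Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(FPKM + 1), with genes at 1 FPKM or more in at least 2 libraries of the comparison and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p below 0.05. A difference on this scale understates the change of low genes. Each comparison with sea level used the 2 groups of its table. Day 14 was compared with day 4 in a fit of the cell type's 3 groups. The difference between cell types is the interstitial minus the alveolar effect in a fit of 4 groups. The 36 gene lists were tested with camera at a preset correlation of 0.01 where at least 4 members were measured. Adjustment was over the lists of a comparison. Members were counted as called over all genes tested and as adjusted over the list alone. Camera tests a list against all other genes and can call it with few members called singly. All camera calls were lost with an estimated correlation, even one of 0.00247 (complement, alveolar day 4), so these losses do not show correlation.

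The groups, comparisons, tests, lists, the rule for named genes and most of the other settings were fixed before the data were examined. The rule takes, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those called whose groups do not overlap and whose higher group has a mean of at least 2 FPKM, leaving out predicted genes, RIKEN clones, pseudogenes, small RNAs and unnamed loci, and adds up to 4 members per list with the smallest p. Where fewer than 10 genes passed, the 5 with the smallest p were added. A few genes taken by the rule are not reported here. The name patterns for clones and small RNAs also left out some genes whose symbols begin with the same letters, such as those of the Rnf and Rnase families. For differences between cell types, groups were taken not to overlap when the hypoxia libraries minus the mean of their own sea level libraries had separate ranges. With 3 libraries against 3, groups do not overlap by chance in 10% of genes in either direction together.

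Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median centring, quantile normalization, the robust setting of eBayes, a joint fit of the cell type, the replicate number as a block, the authors' q-value, fry, an estimated correlation, and each library left out in turn. Where that left 1 alveolar library at sea level, the lone sample was assumed to vary like the other group. Alternatives added after the data were seen were a spline (4 degrees of freedom) on transcript length and GC content removed from each library, a set of 15004 protein-coding genes with under 5% of words shared, no selenocysteine feature and a transcript of at least 1000 bases, both together, the 2 hypoxia groups fitted alone, and the number of the hypoxia libraries as a block shared by the cell types. Overlap between times was set against 20 simulations of unchanged groups, with simulated sea level libraries shared by both times and no library type difference.

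The code was tested on simulated data with 200 changed genes and known folds. For alveolar cells at day 4 against sea level (11378 genes), 64% of 2-fold and 97% of 4-fold changes were recovered. Of 171 calls 5.85% were false. For interstitial cells at day 4 (12778 genes), 10% and 79% were recovered, and 11% of 100 calls were false. In both, camera called 0 lists without an effect and a list raised by 0.5 (adjusted p = 1.34e-11 and 4.2e-10). Correlated genes were not simulated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.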

Results

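Alveolar macrophages (AM), which line the airspaces of the lung, and interstitial macrophages (IM), which lie in the tissue between them, were sorted from the lungs of C57BL/6 mice. Their mRNA was sequenced in bulk. The mice had been kept at sea level or exposed to a simulated altitude of 18000 feet for 4 or 14 days. There were 6 groups and 17 libraries, with 2 alveolar libraries at sea level and 3 in each of the other 5 groups. Values are the authors' FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library). Differences are of log2(FPKM + 1) with the standard error (SE) of the limma fit. Group means are given with the SD. Nothing in the labels says that libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

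Summed FPKM per library lay between 260114 and 716752, and between 11196 and 13289 genes reached 1 FPKM. Depth per library is not given in the sources used here. The step size of low values gave approximate depths of 16.4 to 31.4 M fragments at sea level and 11.5 to 15.2 M in the hypoxia libraries. Genes of small RNAs took 44.1 to 59.6% of the summed FPKM in the 5 sea level libraries and 3.46 to 7.28% in the 12 hypoxia libraries. Mir6236, a microRNA locus, was the highest gene in each of the 5 sea level libraries, with 13.2 to 34.7% of the sum. The median FPKM of the ribosomal protein genes was 10.6 to 23.7 at sea level and 47.5 to 98.9 in the hypoxia libraries. Because the sea level and hypoxia libraries differed in these respects without overlap, the exposure and the library type could not be told apart in any comparison with sea level. The comparisons of day 14 with day 4 do not carry this difference. Replicates correlated across genes at 0.941 to 0.975 in the alveolar groups, 0.784 to 0.869 in interstitial cells at sea level and 0.906 to 0.955 in interstitial cells under hypoxia.

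**Figure D1:**
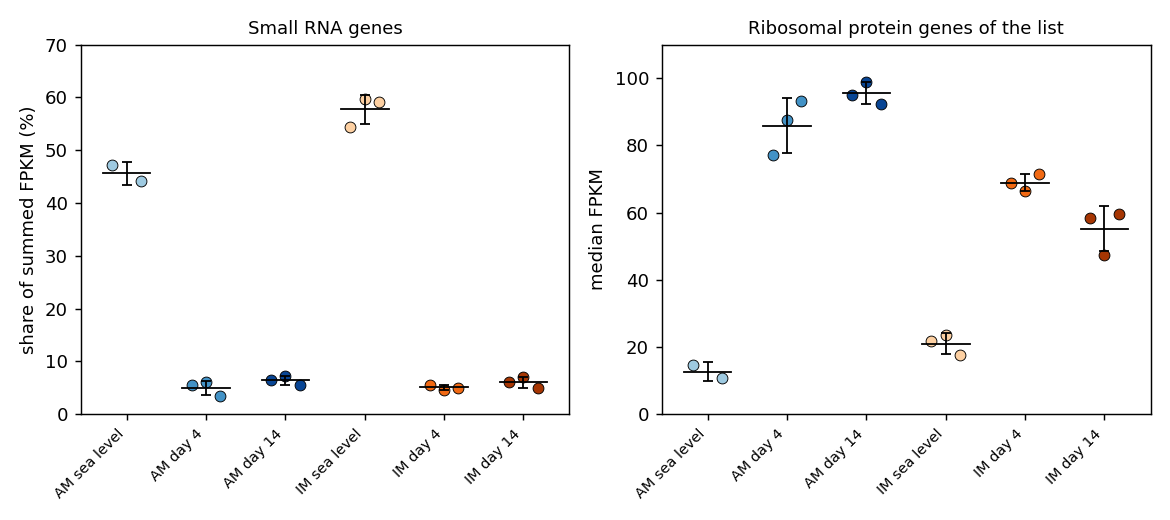
Each point is 1 of the 17 libraries, with the mean of its group as a line and bars for the SD. The left panel gives the percentage of summed FPKM on small RNA genes, 44.1 to 59.6% at sea level and 3.46 to 7.28% under hypoxia, and the right panel gives the median FPKM of ribosomal protein genes, 10.6 to 23.7 at sea level and 47.5 to 98.9 under hypoxia.

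Did the sorted cells carry the genes of their labels at sea level? The tables of the 2 cell types may have been normalized separately, so levels are set side by side as a description without a test. Siglecf, a lectin of alveolar macrophages, stood at 76.8 ± 1.24 FPKM in alveolar cells (n = 2) and 0.486 ± 0.350 in interstitial cells (n = 3). The scavenger receptor gene Marco stood at 17.1 ± 2.23 and 3.10 ± 1.90. Genes typical of interstitial macrophages had the opposite order, with the complement component C1qc at 0.768 ± 0.0113 in alveolar and 685 ± 156 in interstitial cells. The fractalkine receptor Cx3cr1 stood at 0.119 ± 0.0400 and 46.8 ± 10.8. The MHC class II genes Cd74 and H2-Eb1 stood at 127 and 6.72 in alveolar cells against 4330.0 and 494 in interstitial cells.

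Which genes differed in alveolar macrophages after 4 days at altitude? Genes of cholesterol synthesis, oxidative phosphorylation, glycolysis and the ribosome were higher as lists at day 4 (n = 3) than at sea level (n = 2). These calls were lost with an estimated correlation and, for glycolysis, in a restricted gene set. Fdps, which makes farnesyl diphosphate in the cholesterol pathway, rose from 0.350 ± 0.114 to 10.2 ± 3.11 FPKM, by 3.02 ± 0.27 on the log2 scale (limma adjusted p = 0.000728). Il1b, which encodes the cytokine interleukin 1 beta, rose from 14.1 ± 0.198 to 88.6 ± 26.7, by 2.52 ± 0.26 (limma adjusted p = 0.00122). The chemokine gene Ccl17 rose from 1.79 ± 0.458 to 45.5 ± 26.8, by 3.90 ± 0.48 (limma adjusted p = 0.00227). Hilpda, a lipid droplet protein induced by hypoxia, rose by 2.17 ± 0.28 from 4.61 to 24.7 FPKM. The alveolar marker Siglecf fell from 76.8 ± 1.24 to 42.1 ± 2.76, by a log2 difference of -0.86 ± 0.11. Gclm, a subunit of the enzyme that starts glutathione synthesis, fell from 24.8 to 5.07 FPKM with a log2 difference of -2.09 ± 0.12.

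By the rule for named genes, the largest rises at day 4 in alveolar macrophages included Rpl21, Rps4x, Actg1, Rpl39, Rpl41, Rps27rt, Rps28 and Rpl37a. Of these, 7 are genes of ribosomal proteins and Actg1 encodes a cytoplasmic actin. Rpl21 was the highest of these, from 1.06 ± 0.0939 to 61.1 ± 4.55 FPKM, by 4.91 ± 0.13 (limma adjusted p = 8.12e-06). Values of such genes are uncertain because part of their sequence is shared with other genes or pseudogenes. The share was 27.4% of 31-base words for Rpl21 and 57.1% for Actg1. Other genes named here with shared words, and so uncertain, were Spp1 (10.2%), Fdps (13.6%), Gpi1 (16.0%), Mtcp1 (17.7%), Slfn4 (18.3%), Cox5b (32.6%) and Aldoa (34.2%). Among the largest falls, Syt9 was at 57.6 and 41.4 FPKM at sea level, Ppp1r14a at 49.0 and 40.1 and Pnck at 20.5 and 13.2. All 3 were listed at 0 in the 6 alveolar hypoxia libraries. They fell in interstitial cells too, as did Mtcp1, Gtf2i and Tbr1. These falls cannot be told apart from the library type. Txnrd1, a thioredoxin reductase that contains selenocysteine, went from 1531 ± 145 to 109 ± 23.9, a log2 difference of -3.81 ± 0.20 (limma adjusted p = 0.000105). The selenoprotein gene Vimp went from 1164 ± 108 to 97.6 ± 7.41, a log2 difference of -3.56 ± 0.13. Selenoprotein genes varied more between replicates than genes of like level, with a median SD of log2 values of 0.58 against 0.19. Mtcp1 at -3.55 ± 0.27, Gtf2i at -2.99 ± 0.19, Tbr1 at -2.59 ± 0.25 and Afap1l2 at -2.57 ± 0.22 followed. Txnrd3, a related reductase, had a log2 difference of -3.35 ± 0.93 (limma adjusted p = 0.0344). Its call was lost without either sea level library, without day 4 replicate 3, with pseudocount 0.1, without the filter and with the robust setting of eBayes. With any 1 library left out, its log2 difference lay between -4.03 and -2.45.

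Grouped by function, the 23 measured genes of cholesterol biosynthesis rose without exception, also when adjusted over the list alone. Their median lay 1.24 above that of all genes (camera adjusted p = 6.02e-07). Pmvk rose by 2.43 ± 0.16 and Insig1, a regulator of sterol synthesis, by 1.80 ± 0.14. Of 39 ribosomal protein genes 37 rose, 1 fell and 1 was not called, with 37 rising and 1 falling when adjusted over the list alone. The median lay 1.85 above all genes (camera adjusted p = 1.35e-13). In oxidative phosphorylation, 29 of 37 genes rose, 1 fell and 7 were not called (31 and 1 when adjusted over the list alone; median 0.83 above all genes, camera adjusted p = 3.43e-06). Cox5b of complex IV rose by 2.48 ± 0.14, Sdhd of complex II by 2.02 ± 0.15 and the ATP synthase subunit Atp5b by 1.76 ± 0.14. In glycolysis 13 of 19 genes rose and 6 were not called, 13 also adjusted over the list alone (median 0.90 above all genes, camera adjusted p = 0.00157). Gpi1 was at 1.76 ± 0.13 and Aldoa at 1.63 ± 0.14. A restricted set, chosen after the data were seen, kept protein-coding genes with under 5% of words shared, no selenocysteine feature and a transcript of at least 1000 bases. In it glycolysis lay 0.50 above all genes with a camera adjusted p of 0.185, and with the length and GC trend also removed oxidative phosphorylation had adjusted p = 0.0547 (0.52 above with the trend alone removed). These 4 lists had camera adjusted p = 0.676 with an estimated correlation.

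Lists with adjusted p values nearer the threshold in alveolar macrophages at day 4 were complement and coagulation (12 of 21 rose, 1 fell, 8 not called; camera adjusted p = 0.0333), heat shock and immediate early genes (13 of 25 rose, 12 not called; adjusted p = 0.0478) and iron and heme (8 of 18 rose, 10 not called; adjusted p = 0.0478). Markers of interstitial macrophages (13 of 21 rose, 1 fell, 7 not called; camera adjusted p = 0.0356), neutrophils (6 of 12 rose, 6 not called; adjusted p = 0.0333) and endothelium (8 of 13 rose, 5 not called; adjusted p = 0.0333) passed as well. Adjusted over the list alone, 12, 13, 9, 15, 9 and 9 members of these 6 lists rose, in the same order. Each list had an adjusted p of 0.676 with an estimated correlation. Markers of club and ciliated cells (6 of 10 rose, 4 not called, 7 up adjusted over the list alone, camera adjusted p = 0.0664) and of fibroblasts and smooth muscle (7 of 11 rose, 4 not called, 8 up adjusted over the list alone, adjusted p = 0.0822) lay 1.6 and 1.1 above all genes but did not pass. They had adjusted p = 0.0206 and 0.037 with median centring, 0.045 and 0.023 with the length and GC trend removed and 0.0071 and 0.0438 without sea level library E, and fibroblasts had 0.0318 without day 4 replicate 1. The complement component C3 fell from 71.8 to 32.4 with a log2 difference of -1.14 ± 0.18. The neutrophil genes S100a9 and S100a8 rose by 3.29 ± 0.39 and 2.78 ± 0.38, to 12.1 and 37.4 FPKM. Without sea level library F the p-values of the 6 lists were 0.0753, 0.088, 0.0753, 0.0753, 0.0753 and 0.0857. Without sea level library E those of iron and of interstitial markers were 0.0671 and 0.0624. Without day 4 replicate 1 that of iron was 0.0565, and without day 4 replicate 2 those of heat shock, iron, interstitial and neutrophil lists were 0.0885, 0.0741, 0.0507 and 0.0687. With the length and GC trend removed, a choice made after the data were seen, the heat shock and neutrophil lists had adjusted p = 0.18 and 0.0672. In the restricted set the complement, heat shock, iron, neutrophil and endothelial lists had adjusted p = 0.0573, 0.0573, 0.0742, 0.248 and 0.0573, and the first 4 had 0.104, 0.384, 0.1 and 0.384 with the trend also removed. With a pseudocount of 0.1 the heat shock list had adjusted p = 0.0529.

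Inflammatory cytokines were not called as a list at day 4 in alveolar macrophages (12 of 30 genes rose, 1 fell, 17 not called; 12 and 1 adjusted over the list alone; camera adjusted p = 0.057). Hypoxia-inducible genes were not called either (7 of 22 rose, 1 fell, 14 not called; 5 rose adjusted over the list alone; camera adjusted p = 0.37). Markers of alveolar macrophages were not called (9 of 28 rose, 3 fell, 16 not called; 10 and 3 adjusted over the list alone; camera adjusted p = 0.625).

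Over all genes, limma called 5054 of 12641 at day 4 in alveolar macrophages, 3434 higher (67.9%) and 1620 lower. The median of all genes was itself 0.204 higher at day 4, and with each library centred on its median 2405 genes were higher (48.5%) and 2550 lower. With quantile normalization 52.4% of 5098 calls were higher. The count was lower without sea level library E or F, where 124 of the 129 named genes with a call were tested. Without some 1 library 38 lost it. In the restricted set 2814 genes were called.

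Did the picture in alveolar macrophages hold after 14 days? Genes of cholesterol synthesis, oxidative phosphorylation and the ribosome were again higher than at sea level as lists (calls lost with an estimated correlation). Single genes of antigen presentation and the matrix rose. H2-Eb1, an antigen-presenting MHC class II chain, rose from 6.72 ± 1.05 to 37.5 ± 3.15 FPKM, by 2.32 ± 0.13 (limma adjusted p = 8.66e-05). Mmp12, the macrophage elastase, rose by 2.75 ± 0.28, the resistin-like gene Retnla by 2.87 ± 0.29, and Arg1, arginase 1, by 2.24 ± 0.25 from 0.793 to 7.65 FPKM. The lipid receptor Trem2 rose by 2.35 ± 0.14 and the scavenger receptor Stab1 by 2.37 ± 0.15. Il1b stood at 43.8 ± 2.24 FPKM, a rise of 1.57 ± 0.09. The largest rises by the rule included Rpl41, Rpl21, Rpl39, Rps27rt, Actg1, Rpl37a, Rps28, Rps4x and Rplp1, which are uncertain as said above. Rpl41 led with 5.48 ± 0.10 (limma adjusted p = 2.18e-06, 36.2% of words shared). Besides Syt9, Ppp1r14a and Pnck, all listed at 0, the largest falls were in Txnrd3 at -4.08 ± 0.82, Txnrd1 at -3.88 ± 0.09 (limma adjusted p = 3.39e-06), Vimp at -3.46 ± 0.30, Mtcp1 at -3.05 ± 0.17, ANKRD23 at -2.81 ± 0.25, Chic2 at -2.81 ± 0.11 and Gtf2i at -2.70 ± 0.19.

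Cholesterol biosynthesis was high as a list at day 14 in alveolar macrophages (20 of 23 rose, 3 not called; 21 adjusted over the list alone; median 0.70 above all genes, camera adjusted p = 0.00013). Mvd was at 2.52 ± 0.13 and Fdps at 2.40 ± 0.15. Ribosomal protein genes (37 of 39 rose, 1 fell, 1 not called; 38 and 1 adjusted over the list alone; median 1.96 above all genes, camera adjusted p = 1.34e-11) were called as a list. So were oxidative phosphorylation genes (33 of 37 rose, 1 fell, 3 not called; 33 and 1 adjusted over the list alone; median 1.02 above all genes, camera adjusted p = 1.12e-05), with the complex I subunit Ndufa1 up by 2.93 ± 0.17. In glycolysis 14 of 19 genes rose and 5 were not called (15 adjusted over the list alone; median 0.76 above all genes, camera adjusted p = 0.0023, 0.284 in the restricted set). In complement and coagulation 18 of 20 genes rose, 1 fell and 1 was not called (18 and 1 adjusted over the list alone; median 0.73 above all genes, camera adjusted p = 0.0023). Coagulation factor F7 was at 1.74 ± 0.08 and C1qc at 1.87 ± 0.16. Markers of interstitial macrophages were higher (19 of 21 rose, 1 fell, 1 not called; 19 and 1 adjusted over the list alone; median 1.24 above all genes, camera adjusted p = 0.00133). The selenoprotein gene Sepp1 fell (-2.15 ± 0.13). Interstitial cells in the sort could carry these and H2-Eb1 but were not tested for. These 6 lists had an adjusted p of 0.47 with an estimated correlation.

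Heat shock and immediate early genes (16 of 25 rose, 9 not called; 17 adjusted over the list alone; camera adjusted p = 0.025) and neutrophil markers (8 of 9 rose, 1 not called; 9 adjusted over the list alone; adjusted p = 0.0231) also passed at day 14 in alveolar macrophages. So did endothelial markers (11 of 14 rose, 3 not called; 11 adjusted over the list alone; adjusted p = 0.0291) and inflammatory cytokines (16 of 28 rose, 1 fell, 11 not called; 16 and 1 adjusted over the list alone; adjusted p = 0.038). Each had adjusted p = 0.47, or 0.6 for endothelium, with an estimated correlation. MHC class II genes as a list did not pass (8 of 12 rose, 1 fell, 3 not called; 8 and 1 adjusted over the list alone; camera adjusted p = 0.0559), nor did matrix and growth factor genes (13 of 19 rose, 1 fell, 5 not called; 13 and 1 adjusted over the list alone; camera adjusted p = 0.0551). Endothelial markers had adjusted p = 0.0944 without sea level library F and 0.0504 in the restricted set. The inflammatory list had adjusted p = 0.0817 and 0.0562 without sea level libraries E and F, and 0.0671 without day 14 replicate 3. It had 0.0861 with median centring and 0.425 with the length and GC trend removed, under which the heat shock and neutrophil lists had adjusted p = 0.0932 and 0.0798. In the restricted set the inflammatory list had 0.14, and with the trend also removed the inflammatory and heat shock lists had 0.36 and 0.28. Oxidative phosphorylation lay 0.56 above all genes with the trend removed, and the heat shock median of 0.32 was 0.49, 0.52 and 0.47 without sea level library F and day 14 replicates 1 and 3.

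At day 14 limma called 6514 of 12733 genes in alveolar macrophages, 4853 higher (74.5%) and 1661 lower. The median of all genes was 0.288 higher. With median centring 2943 genes were higher (47.8%) and 3210 lower. Quantile normalization gave 51.5% of 6310 calls higher. The count was 3911 without sea level library F. Of 134 named genes with a call (130 tested without E or F), 6 lost it without some 1 library. With the length and GC trend removed 20 lost it or turned sign.

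Which genes differed in interstitial macrophages after 4 days at altitude? Arginase and osteopontin rose and a secreted phospholipase fell. Arg1, which turns arginine into ornithine, was at 0.763, 2.33 and 1.84 FPKM in the 3 sea level libraries and 261, 107 and 168 in the 3 day 4 libraries, a rise of 6.04 ± 0.38 (limma adjusted p = 0.000229). Spp1, which encodes the secreted matrix protein osteopontin, rose from 7.27 ± 1.81 to 108 ± 4.33, by 3.75 ± 0.20 (limma adjusted p = 0.000115). Pla2g2d, a secreted phospholipase A2, fell from 50.9 ± 4.43 to 2.49 ± 1.06, a log2 difference of -3.93 ± 0.26 (limma adjusted p = 0.000238). Il1rn, the antagonist of the interleukin 1 receptor, rose from 22.6 ± 3.44 to 113 ± 46.0, by 2.19 ± 0.33 (limma adjusted p = 0.00856). Il1b rose by 1.59 ± 0.27 (limma adjusted p = 0.0141) and the cytokine Osm by 1.97 ± 0.30, calls lost without day 4 replicate 2 and day 4 replicate 3, respectively. With any 1 library left out, the log2 difference of Il1b lay between 1.34 and 1.76 and that of Osm between 1.80 and 2.20. The call of Il1b was also lost with the length and GC trend removed.

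The other genes taken by the rule in interstitial macrophages at day 4 included Rpl21 at 5.49 ± 0.28 and Scgb3a1, a secretoglobin of airway epithelium, at 4.69 ± 0.97 (limma adjusted p = 0.0264). They also included Rps4x, Rpl39, Nme2 and Rpl29, which share sequence with copies and are uncertain. Among the falls, Syt9 was at 127, 243 and 108 FPKM at sea level and listed at 0, 0.0366 and 0 at day 4. Ppp1r14a was at 66.6, 95.8 and 55.8 and listed at 0 in the 3 day 4 libraries, and Pnck was at 57.6, 86.2 and 40.9 and listed at 0 in the 6 interstitial hypoxia libraries. Mtcp1 at -4.55 ± 0.47, Vimp at -4.54 ± 0.88, Tbr1 at -4.32 ± 0.31, Gtf2i at -4.10 ± 0.27, Txnrd1 at -3.46 ± 0.66 and Jade1 at -3.48 ± 0.23 were the other falls. Jade1 stood at 45.2 ± 10.4 FPKM at sea level and 3.09 ± 0.306 at day 4. The calls of Vimp, Txnrd1 and Scgb3a1 were lost without any 1 of the 3 day 4 replicates. They were also lost without sea level library A, B and C, respectively, and all 3 without the filter on low values. Their log2 differences with any 1 library left out lay between -5.59 and -3.74 for Vimp, -4.28 and -3.04 for Txnrd1, and 3.62 and 5.73 for Scgb3a1.

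In glycolysis, 10 of 19 genes rose in interstitial macrophages at day 4 and 9 were not called (12 adjusted over the list alone; median 1.06 above all genes, camera adjusted p = 8.22e-07, and adjusted p = 0.59 with an estimated correlation). Aldoa, an aldolase, rose by 1.67 ± 0.17, and Ldha, lactate dehydrogenase A, by 1.84 ± 0.19, although 34.2% of the words of Ldha are shared with other genes. Hypoxia-inducible genes were called as a list with 2 of 24 members up and 22 not called (2 adjusted over the list alone; median 0.54 above all genes, camera adjusted p = 0.0147, and adjusted p = 0.522 with an estimated correlation). The cytokine gene Mif, which shares 46.1% of its words, rose by 3.10 ± 0.47. Ribosomal protein genes had 27 of 39 members up and 12 not called (34 adjusted over the list alone; median 1.57 above all genes, camera adjusted p = 1.53e-18, and adjusted p = 0.354 with an estimated correlation). In oxidative phosphorylation 10 of 37 rose, 1 fell and 26 were not called (17 and 1 adjusted over the list alone; median 0.64 above all genes, camera adjusted p = 0.00027, and adjusted p = 0.602 with an estimated correlation). The median was 0.37 (adjusted p = 0.0459) without sea level library A, 0.32 with the length and GC trend removed and 0.42 in the restricted set, where that of glycolysis was 0.58. Sdhd was at 2.22 ± 0.24, Atp5b at 1.82 ± 0.19 and Sdha, another subunit of complex II, at -2.12 ± 0.31.

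Cell cycle genes were called as a list in interstitial macrophages at day 4 with 1 of 34 members up and 33 not called (no member adjusted over the list alone, median 0.62 above all genes, camera adjusted p = 0.00524, and adjusted p = 0.789 with an estimated correlation). Without day 4 replicate 2 the median was 0.38 and the camera adjusted p 0.0939, and without day 4 replicate 1 they were 1.03 and 2.91e-09. Interferon-stimulated genes were not called (1 of 34 rose, 33 not called; none adjusted over the list alone; median 0.49 above all genes, camera adjusted p = 0.118), but had a median of 1.07 and an adjusted p of 2.91e-09 without day 4 replicate 1. Markers of T and NK cells lay below all genes by a median of -1.11 (1 of 14 fell, 13 not called; 2 adjusted over the list alone; camera adjusted p = 0.000616, and adjusted p = 0.602 with an estimated correlation). Classical monocyte markers were not called (2 of 18 rose, 16 not called; 2 adjusted over the list alone; median 0.73 above all genes, camera adjusted p = 0.0961), but had a median of 1.04 and an adjusted p of 0.0374 without day 4 replicate 1, and a median of 0.33 without sea level library A. Inflammatory cytokines were not called (4 of 31 rose, 1 fell, 26 not called; 6 and 1 adjusted over the list alone; camera adjusted p = 0.608). Interstitial macrophage markers were not called either (2 of 29 rose, 2 fell, 25 not called; 3 and 4 adjusted over the list alone; camera adjusted p = 0.124).

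Of 13915 genes tested in interstitial macrophages at day 4, limma called 1460, 1072 higher (73.4%) and 388 lower. The median of all genes was 0.104 higher. The count fell to 917, 627 and 517 without day 4 replicates 1, 2 and 3. Of the 85 named genes with a call, 48 lost it without some 1 library. The count was 881 without the filter on low values, 2316 in a joint fit of the 3 interstitial groups, and 350 in the restricted set.

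**Figure D2:**
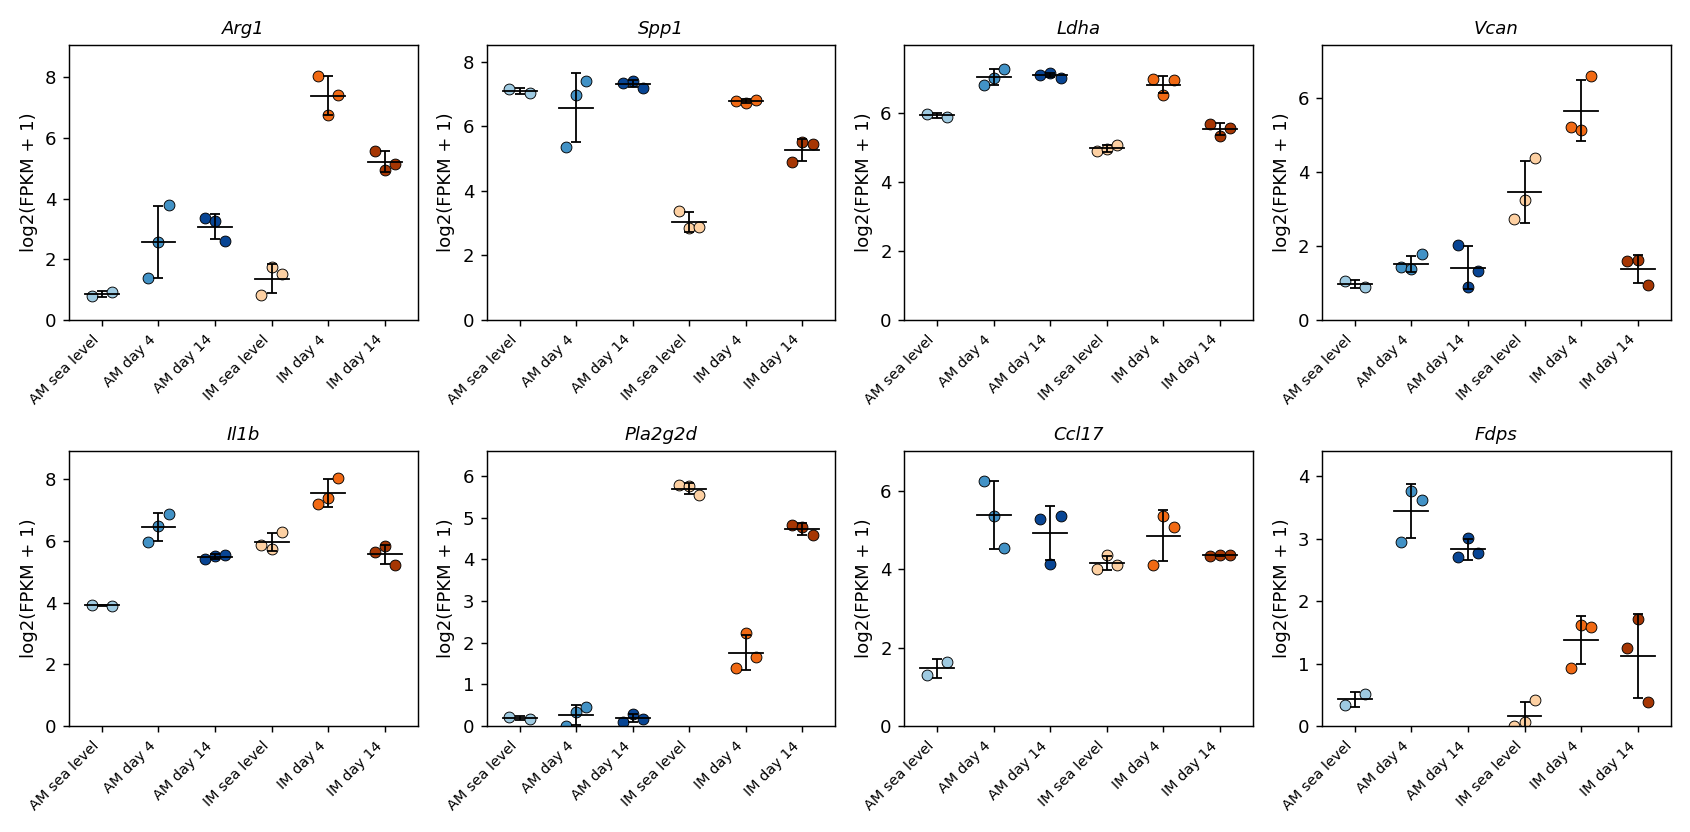
Values of log2(FPKM + 1) are shown for Arg1, Spp1, Ldha, Vcan, Il1b, Pla2g2d, Ccl17 and Fdps, with each library as a point, the mean of each of the 6 groups as a line and bars for the SD. Arg1 in interstitial macrophages is at 1.65 FPKM at sea level, 179 at day 4 and 37.0 at day 14, and Fdps in alveolar macrophages is at 0.350, 10.2 and 6.14.

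Which genes differed in interstitial macrophages after 14 days? Arg1 and Spp1 were higher than at sea level, and inflammatory cytokines and interferon-stimulated genes were lower as lists (calls lost with an estimated correlation). Arg1 stood at 37.0 ± 8.99 FPKM (n = 3), a rise of 3.87 ± 0.30 (limma adjusted p = 0.000824), and Spp1 at 38.3 ± 8.63, a rise of 2.25 ± 0.25 (limma adjusted p = 0.00327). Ptgs2, which encodes the inducible cyclooxygenase, fell from 34.0 ± 7.35 to 4.56 ± 1.74 with a log2 difference of -2.67 ± 0.28 (limma adjusted p = 0.0029). The integrin gene Itgal fell by -1.94 ± 0.27, but its list, chemokine receptors and adhesion, was not called (2 of 21 fell, 19 not called; 2 adjusted over the list alone; camera adjusted p = 0.171). Gtf2a1, a general transcription factor, rose from 4.71 to 58.2, by 3.41 ± 0.30. Stag3, a cohesin subunit, fell from 18.0 to 0.898, a log2 difference of -3.31 ± 0.29. Prg4, lubricin, was at 41.8, 301 and 170.4 at sea level and 7.77, 12.4 and 7.90 at day 14 (log2 difference -3.68 ± 0.66, limma adjusted p = 0.0226). Its call was lost without sea level library C, without any 1 of the 3 day 14 replicates, without the filter and in the joint fit, with log2 differences between -4.48 and -3.08 with any 1 library left out.

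The remaining genes of the rule in interstitial macrophages at day 14 included Rpl21 at 5.27 ± 0.28, Rpl39, Rps4x, Rps28, Rpl29 and Nme2 among the rises, which share sequence with copies. Among the falls were Mtcp1 at -4.41 ± 0.28, Tbr1 at -4.25 ± 0.32, Txnrd1 at -3.90 ± 0.71, Gtf2i at -3.88 ± 0.27 and Vimp at -4.54 ± 0.87. The calls of Vimp and Txnrd1 were lost without any 1 of the 3 day 14 replicates, and also without sea level library A for Vimp and B for Txnrd1. Their log2 differences lay between -5.59 and -3.74, and -4.72 and -3.48 with any 1 library left out. Syt9 was listed at 0.0294, 0 and 0 and Ppp1r14a at 1.23, 2.08 and 0.193 FPKM at day 14.

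As lists, interferon-stimulated genes lay below all genes by a median of -0.65 in interstitial macrophages at day 14 (3 of 34 fell, 31 not called; 1 up and 3 down adjusted over the list alone; camera adjusted p = 4.55e-06). The interferon regulator Irf7 was at -1.90 ± 0.38 (limma adjusted p = 0.0312). Inflammatory cytokines lay below by -0.44 (5 of 30 fell, 25 not called; 2 up and 5 down adjusted over the list alone; camera adjusted p = 0.00409, 0.0722 in the restricted set). The chemokine gene Ccl12 fell from 254 ± 72.1 to 77.0 ± 18.0 FPKM, and interleukin 6 (Il6) was at -1.26 ± 0.24. Classical monocyte markers lay below by -0.91 (1 of 18 rose, 2 fell, 15 not called; 3 up and 8 down adjusted over the list alone; camera adjusted p = 0.00176) and nonclassical monocyte markers by -0.60 (3 of 16 fell, 13 not called; 3 adjusted over the list alone; camera adjusted p = 0.00359). T and NK cell markers lay below by -1.07 (1 of 13 fell, 12 not called; 1 adjusted over the list alone; camera adjusted p = 0.00176) and neutrophil markers by -0.77 (1 of 14 fell, 13 not called; 1 adjusted over the list alone; camera adjusted p = 0.0253). These 6 lists had an adjusted p of 0.528 with an estimated correlation. The calls of Irf7 and Il6 were lost without sea level library B and without any 1 of the 3 day 14 replicates, and that of Ccl12 without day 14 replicates 1 and 2. Their log2 differences with any 1 library left out lay between -2.29 and -1.54, -1.42 and -1.08, and -1.90 and -1.49. The call of the neutrophil list was lost without sea level libraries A and B and day 14 replicates 1 and 3 (adjusted p = 0.0803, 0.0556, 0.16 and 0.0539). The inflammatory median was -0.29 without day 14 replicate 1 and that of nonclassical monocytes -0.38 without sea level library C.

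Markers of endothelium (1 of 21 rose, 20 not called; 1 adjusted over the list alone; median 1.21 above all genes, camera adjusted p = 0.00359) lay above all genes in interstitial macrophages at day 14. So did those of fibroblasts and smooth muscle (18 not called; 2 up adjusted over the list alone; 1.68 above, adjusted p = 0.00603) and of club and ciliated cells (14 not called; 6 up adjusted over the list alone; 1.18 above, adjusted p = 0.0285). These 3 lists had adjusted p = 0.75, 0.75 and 0.528 with an estimated correlation. Without sea level library B the 3 lists had adjusted p = 0.0604, 0.113 and 0.0834. Without sea level library C the fibroblast and club lists had 0.0649 and 0.0725, and the club list had 0.37 without day 14 replicate 3 and 0.0518 in the restricted set. Median levels of the fibroblast list were 3.88, 1.43 and 1.21 in sea level libraries A, B and C and 4.65, 3.56 and 2.88 in the day 14 libraries. Ribosomal protein genes lay above all genes by 1.28 (20 of 39 rose, 19 not called; 30 adjusted over the list alone; camera adjusted p = 6e-16, and adjusted p = 0.321 with an estimated correlation). Glycolysis lay 0.21 above (4 of 19 rose, 15 not called; 5 adjusted over the list alone; camera adjusted p = 0.0285, and adjusted p = 0.528 with an estimated correlation), with Aldoa at 1.22 ± 0.15. Its adjusted p was 0.164 without sea level library B, 0.0755 without day 14 replicate 3 and 0.694 in the restricted set, and its median 0.37 and 0.38 without day 14 replicates 1 and 2.

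In all, limma called 1083 of 14340 genes in interstitial macrophages at day 14, 711 higher (65.7%) and 372 lower, with a median shift of 0.131. With median centring 515 were higher (54.2%) and 435 lower. The count was 396, 362 and 361 without day 14 replicates 1, 2 and 3, 550 without the filter and 195 in the restricted set. Of the 78 named genes with a call, 46 lost it without some 1 library.

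How far did the changes at day 4 and day 14 go together? Across 12260 genes tested at both times in alveolar macrophages, log2 differences from sea level correlated at r = 0.971. Simulated unchanged groups, with simulated sea level libraries shared by both times, gave 0.615. The covariance was 1.52 against 0.0462 simulated. Both times called 3163 of the same genes higher and 1272 lower, where independent lists would share 1293 and 219. By limma, 0 genes were called in opposite directions. In interstitial macrophages r was 0.849 over 13400 genes (simulated 0.515) and the covariance 0.874 (simulated 0.0808). There were 570 genes higher at both times and 243 lower (independent lists 52.6 and 10.8) and 1 in opposite directions. Genes are not independent replicates, and with 2 or 3 sea level libraries these could not be split, so part of the excess may come from the shared controls.

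Did alveolar macrophages differ between day 14 and day 4? Wfdc17, which encodes a secreted protein with a whey acidic protein domain, fell from 140.2 ± 4.82 to 60.0 ± 6.59 FPKM, a log2 difference of -1.22 ± 0.11 (limma adjusted p = 0.0333). The other call of 13331 genes, named after its values were seen, was Gm25492 (chromosome 5, 135053988 to 135054116), a small Cajal body RNA listed at 0 in the 3 day 4 libraries and at 31.5, 33.0 and 9.91 FPKM at day 14 (limma adjusted p = 0.0333). Both calls were lost without any 1 of the 3 day 4 replicates or without day 14 replicate 1, that of Wfdc17 also without day 14 replicate 2 (log2 differences between -1.29 and -1.13). The counts without day 4 replicates 1, 2 and 3 and day 14 replicates 1, 2 and 3 were 0, 7, 3, 4, 9 and 5. At an unadjusted p below 0.05 limma gave 1822 genes. The next genes by p, 1700110I07Rik, Gm22478 and Gm20091, did not pass (limma adjusted p = 0.0544, 0.0544 and 0.0706).

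Cholesterol biosynthesis genes lay below all genes at day 14 against day 4 in alveolar macrophages by a median of -0.63 (23 not called; 13 fell adjusted over the list alone; camera adjusted p = 2.88e-18, and adjusted p = 0.396 with an estimated correlation). Pmvk went from 21.5 ± 1.69 to 12.6 ± 1.10 FPKM and Insig1 from 21.5 ± 2.65 to 14.5 ± 0.730. Markers of club and ciliated cells (10 not called, none adjusted over the list alone; median -0.67, camera adjusted p = 3.91e-05), of fibroblasts and smooth muscle (11 not called, 2 fell adjusted over the list alone; -0.50, adjusted p = 0.000119) and of classical monocytes (15 not called, 1 up and 1 down adjusted over the list alone; -0.26, adjusted p = 0.00563) lay lower at day 14. So did those of neutrophils (12 not called, 1 up and 5 down adjusted over the list alone; -0.46, adjusted p = 0.0131) and of alveolar epithelium (17 not called, none adjusted over the list alone; -0.28, adjusted p = 0.0385). MHC class II genes (12 not called, none adjusted over the list alone; 0.59, adjusted p = 0.0135) and oxidative phosphorylation genes (37 not called, none adjusted over the list alone; 0.09, adjusted p = 0.0362) lay higher. With an estimated correlation the adjusted p was 0.396 for classical monocytes, 0.415 for club, fibroblast and neutrophil markers and 0.644 for the other 3 lists.

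Of these lists, the monocyte list had adjusted p = 0.109 without day 4 replicate 1 and a median of -0.41 without day 4 replicate 3. The fibroblast median was -0.81 and -0.24 without day 4 replicates 1 and 2. The neutrophil list had adjusted p = 0.109 and 0.96 without day 4 replicates 1 and 2, with medians of 0.06 and 0.14 above all genes. It had 0.0951 with median centring, 0.0866 with the length and GC trend removed and 0.0872 in the restricted set. The epithelial list had adjusted p = 0.449 and 0.0783 without day 4 replicates 2 and 3, 0.135 without day 14 replicate 3, 0.11 with median centring, 0.0866 with the trend removed and 0.0525 with a pseudocount of 0.1. In the same comparison of alveolar macrophages, the MHC class II list had adjusted p = 0.0635 without day 4 replicate 1 and 0.0729 without day 14 replicate 3. Oxidative phosphorylation had adjusted p = 0.0832 and 0.262 without day 4 replicates 1 and 2. It had 0.0568, 0.0538 and 0.0797 without day 14 replicates 1, 2 and 3, 0.0951 with median centring, 0.126 with the trend removed and 0.521 in the restricted set.

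Did interstitial macrophages differ between day 14 and day 4? Pla2g2d rose back from 2.49 ± 1.06 to 25.5 ± 2.39 FPKM (log2 difference 2.96 ± 0.22, limma adjusted p = 0.00246), against 50.9 ± 4.43 at sea level. Vcan, the matrix proteoglycan versican, fell from 55.1 ± 34.8 to 1.66 ± 0.639 with a log2 difference of -4.26 ± 0.49 (limma adjusted p = 0.0362). Il1b fell from 192 ± 62.1 to 46.9 ± 10.1 (-1.99 ± 0.26, limma adjusted p = 0.0414). The chemokine receptor Ccr1 fell by a log2 difference of -1.77 ± 0.20 and the C-type lectin Clec4e by -2.92 ± 0.35. The schlafen gene Slfn4 fell by -3.53 ± 0.45. The limma adjusted p of these 3 genes lay between 0.0362 and 0.0414. Ldha fell from 112 ± 18.6 to 45.2 ± 5.58 (-1.29 ± 0.17, limma adjusted p = 0.0417). Hepacam2, an adhesion molecule, rose from 1.04 to 5.83 FPKM (1.77 ± 0.23). Gm27818, an unnamed RNA taken after its values were seen, was at 5.11, 6.01 and 5.22 FPKM at day 4 and listed at 0 in the day 14 libraries (limma adjusted p = 0.00246). Arg1 and Spp1 did not pass (log2 differences -2.18 ± 0.35 and -1.50 ± 0.21, limma adjusted p = 0.077 and 0.0533).

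Limma called 13 of 15038 genes in this comparison of interstitial macrophages, 3 higher and 10 lower, and 2165 at an unadjusted p below 0.05. The counts without sea level libraries A and B were 50 and 3, without day 4 replicates 1 and 3 they were 66 and 3, and without day 14 replicates 1 and 2 they were 5 and 7. The calls of Vcan, Clec4e, Ldha, Il1b, Ccr1, Slfn4 and Hepacam2 were lost without sea level library B, day 4 replicate 3 or any 1 of the 3 day 14 replicates. Those of Il1b, Ccr1, Slfn4 and Hepacam2 were also lost without day 4 replicate 2. With any 1 library left out, the log2 differences lay between -4.51 and -3.79 for Vcan, -2.16 and -1.74 for Il1b, -1.86 and -1.68 for Ccr1, and -3.26 and -2.64 for Clec4e. They lay between -3.97 and -3.12 for Slfn4, -1.43 and -1.19 for Ldha, and 1.58 and 1.87 for Hepacam2. Pla2g2d passed without any 1 of the 9 libraries. A fit of the day 4 and day 14 libraries alone, added after the data were seen, called 44 genes, 12 of them shared.

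Among the lists, glycolysis lay lower at day 14 than at day 4 in interstitial macrophages by a median of -0.73 (1 of 20 fell, 19 not called; 13 adjusted over the list alone; camera adjusted p = 9.9e-10, and adjusted p = 0.113 with an estimated correlation). Classical monocyte markers lay lower by -1.62 (2 of 18 fell, 16 not called; 1 up and 10 down adjusted over the list alone; camera adjusted p = 2.15e-09, and adjusted p = 0.092 with an estimated correlation) and interferon-stimulated genes by -1.04 (34 not called; 6 fell adjusted over the list alone; adjusted p = 6.05e-12, and 0.516). Inflammatory cytokines lay lower by -0.48 (2 of 31 fell, 29 not called; 6 adjusted over the list alone; adjusted p = 1.08e-05, and 0.092) and cell cycle genes by -0.69 (34 not called; 1 fell adjusted over the list alone; adjusted p = 8.95e-09, and 0.516). Oxidative phosphorylation genes (37 not called; median -0.36, camera adjusted p = 5.43e-06, and 0.459 with an estimated correlation), ribosomal protein genes (39 not called; -0.31, adjusted p = 1.1e-05, and 0.337) and lysosome genes (30 not called; -0.28, adjusted p = 0.0225, and 0.609) lay lower with no member called adjusted over the list alone. Chemokine receptors and adhesion genes lay lower by -0.35 (2 of 21 fell, 19 not called; 3 up and 7 down adjusted over the list alone; camera adjusted p = 0.0398, and 0.328 with an estimated correlation).

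Markers of fibroblasts and smooth muscle lay higher at day 14 than at day 4 in interstitial macrophages by a median of 2.45 (18 not called; 13 rose adjusted over the list alone; camera adjusted p = 8.78e-12, and adjusted p = 0.475 with an estimated correlation) and those of endothelium by 1.53 (21 not called; 14 rose adjusted over the list alone; adjusted p = 1.09e-10, and 0.496). Those of alveolar epithelium lay higher by 0.94 (18 not called; 3 up and 1 down adjusted over the list alone; adjusted p = 0.00443, and 0.609) and those of interstitial macrophages by 0.33 (29 not called, none adjusted over the list alone; adjusted p = 0.00443, and 0.516). Median levels of the fibroblast list were 0.705, 2.03 and 1.81 in the 3 day 4 libraries. Those of the interferon list were 2.45, 3.85 and 4.32 at day 4 and 2.36, 2.27 and 2.32 at day 14, and those of the cell cycle list 1.54, 2.87 and 2.85 and then 1.37, 1.55 and 1.80. The lysosome list had adjusted p = 0.549 without day 4 replicate 1 and 0.157 without day 14 replicate 1, and interstitial markers had 0.0514 without day 14 replicate 3. Without day 4 replicate 1 the cell cycle median was -1.20 and the chemokine receptor median -0.18. That of alveolar epithelium was 0.52 and 1.41 without day 14 replicates 1 and 3. The chemokine receptor list had 0.0681, 0.0603 and 0.0781 without sea level libraries A, B and C, 0.0595 and 0.0861 without day 14 replicates 1 and 3, 0.0775 with median centring and 0.0508 with the length and GC trend removed. In the fit of day 4 and day 14 alone the lysosome and chemokine receptor lists had adjusted p = 0.0679 and 0.129, and in the restricted set with the trend removed 0.0641 and 0.159.

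**Figure D3:**
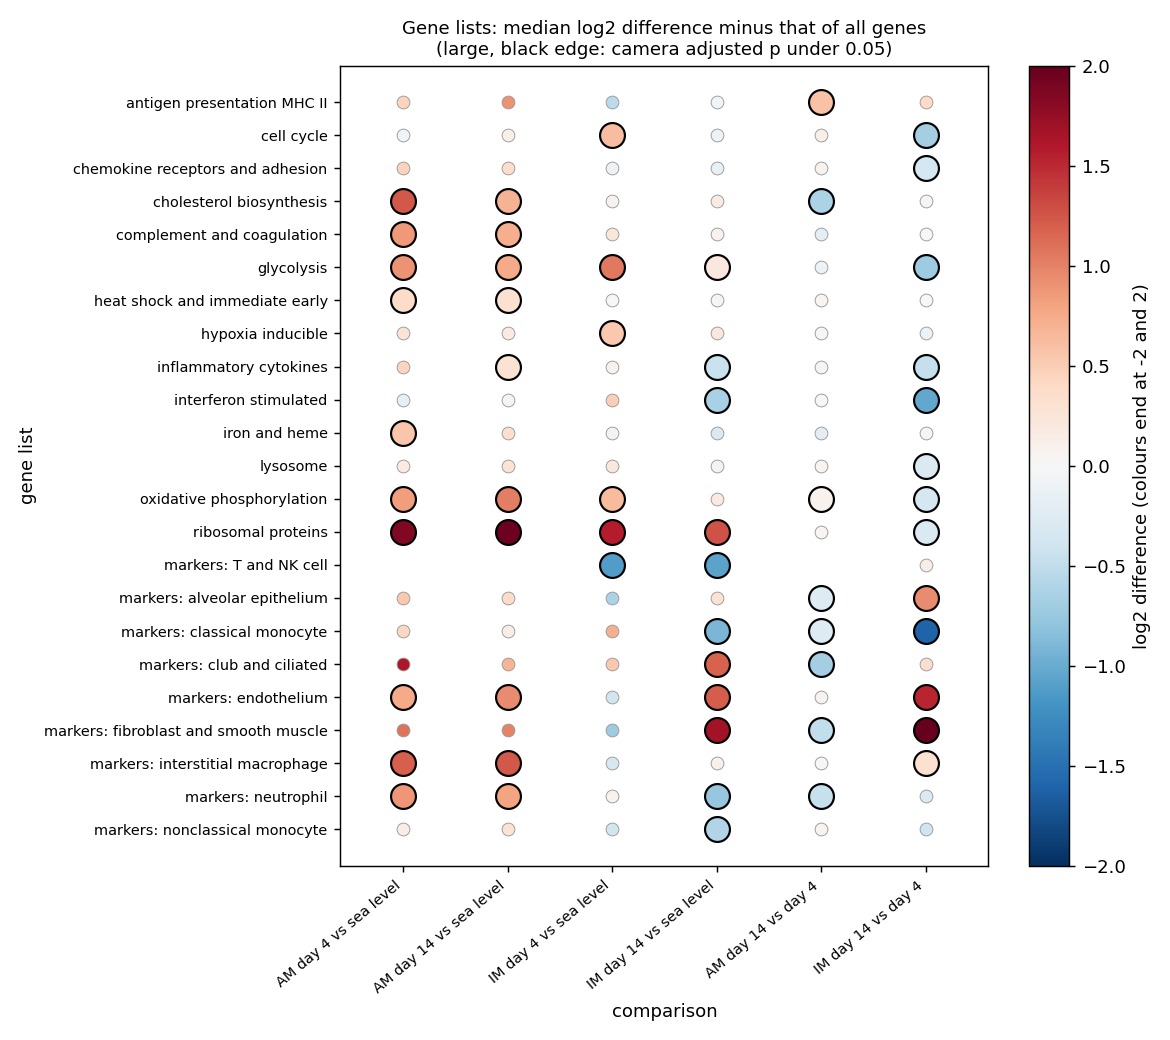
Each dot is 1 of 23 gene lists in 1 of 6 comparisons, coloured by the median log2 difference of its members minus that of all genes, with colours that end at -2 and 2. Large dots with a black edge had a camera adjusted p below 0.05, such as cholesterol biosynthesis in alveolar macrophages at day 4 (1.24) and at day 14 against day 4 (-0.63), and all such calls were lost with an estimated correlation.

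Did the change from sea level to day 4 differ between the cell types? The change, called the effect here, was tested as interstitial minus alveolar, and the library type stays a possible cause. Spp1 differed by 4.27 ± 0.64 (limma adjusted p = 0.00829). Its means were 136 ± 8.95 and 110.4 ± 65.0 FPKM in alveolar cells at sea level and day 4 against 7.27 ± 1.81 and 108 ± 4.33 in interstitial cells. Arg1 differed by 4.30 ± 0.82 (limma adjusted p = 0.0352), with alveolar values of 0.707 and 0.878 at sea level and 1.63, 4.95 and 12.7 at day 4. Il1rn differed by 2.38 ± 0.42 (limma adjusted p = 0.0221) and Gclm by 2.32 ± 0.37. Pla2g2d differed by -4.00 ± 0.35 (limma adjusted p = 0.000128) and Ccl17 by -3.21 ± 0.64 (limma adjusted p = 0.042). Gpx3, a secreted glutathione peroxidase with selenocysteine, was at 1104, 292 and 793 FPKM in interstitial cells at sea level and 264, 116 and 52.3 at day 4, and differed by -5.30 ± 0.94 (limma adjusted p = 0.0227).

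Cholesterol biosynthesis genes had lower differences in interstitial than in alveolar macrophages at day 4 by a median of -1.13 relative to all genes (1 of 23 lower, 22 not called; 16 adjusted over the list alone; camera adjusted p = 2.44e-11, and adjusted p = 0.336 with an estimated correlation). Interstitial macrophage markers did so by -0.81 (29 not called; 12 adjusted over the list alone; camera adjusted p = 2.9e-07, and 0.336 with an estimated correlation) and ribosomal protein genes by -0.62 (4 of 39 lower, 35 not called; 1 up and 17 down adjusted over the list alone; camera adjusted p = 9.12e-08, and 0.336). In all, limma called 208 of 15243 genes, 138 with a higher and 70 with a lower interstitial effect (66.3% higher, and 79.1% of 201 with median centring). The count was 9 and 4 without alveolar sea level libraries E and F and 656 and 314 without interstitial sea level libraries A and C. Of the 31 named genes with a call, 30 lost it without some 1 library, Arg1, Spp1, Il1rn, Gclm, Ccl17 and Gpx3 among them. Their differences in this order then lay between 3.71 and 4.90, 3.66 and 4.69, 2.10 and 2.73, 2.05 and 2.51, -3.64 and -2.78, and -5.88 and -4.73, while Pla2g2d kept it.

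Did the change from sea level to day 14 differ between the cell types? Spp1 again had the higher interstitial effect, by 2.03 ± 0.29 (limma adjusted p = 0.00507). Ptgs2 had the lower, by -3.29 ± 0.49 (limma adjusted p = 0.00615). So had Ccl17, by -3.26 ± 0.43 (limma adjusted p = 0.00317), and Selp, P-selectin, by -3.24 ± 0.37 (limma adjusted p = 0.00122). Interstitial macrophage markers had lower interstitial differences by a median of -0.82 relative to all genes (12 of 29 lower, 17 not called; 1 up and 16 down adjusted over the list alone; camera adjusted p = 4.87e-10, and adjusted p = 0.0886 with an estimated correlation) and inflammatory cytokines by -0.72 (10 of 31 lower, 21 not called; 14 adjusted over the list alone; adjusted p = 1.07e-07, and 0.0886; -0.46 in the restricted set). MHC class II genes had lower ones by -0.83 (7 of 15 lower, 8 not called; 8 adjusted over the list alone; adjusted p = 3.35e-06, and 0.0965) and ribosomal protein genes by -0.97 (18 of 39 lower, 21 not called; 1 up and 25 down adjusted over the list alone; adjusted p = 4.61e-13, and 0.0886). Fibroblast and smooth muscle markers had higher interstitial differences, by 1.14 (18 not called, none adjusted over the list alone; camera adjusted p = 0.000668, and 0.479; 2.03 without interstitial sea level library A).

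Limma called 596 of 15720 genes for the difference of the day 14 effect, 156 with a higher (26.2%) and 440 with a lower interstitial effect, around a median of -0.148. With median centring 307 were called, 162 higher (52.8%) and 145 lower, and with quantile normalization 299, of which 57.5% were higher. The count was 121 and 6 without alveolar sea level libraries E and F, and 260, 264 and 286 without alveolar day 14 replicates 1, 2 and 3. It was 1799 without interstitial sea level library A, and 360 and 367 without interstitial day 14 replicates 2 and 3. Of the 74 named genes with a call, 69 lost it without some 1 library. Spp1 lost it without alveolar library E or F and Ptgs2, Ccl17 and Selp without alveolar library F. The differences then lay between 1.92 and 2.23 for Spp1, -3.62 and -3.11 for Ptgs2, -3.65 and -3.04 for Ccl17, and -3.42 and -2.95 for Selp.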

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

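Of the tests in this part, the removal of the length and GC trend from ribosomal protein genes and the counts over other splits of the samples were set before their results were seen, and the others were chosen after the result was seen.

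Ribosomal protein genes were higher in the hypoxia libraries of both cell types, by a median of 1.85 above all genes in alveolar cells at day 4. With the length and GC trend removed, the smallest of the 4 medians against sea level was still 1.13, and among the 6 members with under 10% shared words the smallest was 0.715, which argues against either as the whole cause. What stays open is the preparation or processing of the sea level libraries, which had a share of small RNA genes at least 36.8 percentage points above every hypoxia library. It cannot be told apart from the exposure because the 5 sea level libraries are all on one side of that gap. An effect of the exposure itself was not tested.

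Selenoprotein genes had median differences from sea level of -1.09, -0.996, -2.31 and -1.75 in alveolar cells at day 4 and 14 and interstitial cells at day 4 and 14. Limma called 10 of 19, 9 of 19, 6 of 19 and 7 of 20 of them lower and 2, 2, 0 and 0 higher, and they were not tested as a list. Their values between replicates had a median SD of 0.58 in log2 units over 20 genes, against 0.19 in 10000 sets of genes of like level, the highest of which reached 0.273, so the values may not be reliable estimates of the mRNA. The sea level preparation (gap of 36.8 points) cannot be told apart here either, since it divides the libraries as the exposure does. A response of selenoprotein genes to the exposure stays open and untested.

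Arg1 and Spp1 were higher in interstitial macrophages at day 4, by 6.04 ± 0.38 and 3.75 ± 0.20. A single library as cause is argued against, because with any 1 left out the highest limma adjusted p of Arg1 and Spp1 was 0.00344. So are alveolar macrophages in the interstitial sort. The share of 4.62% that 27 alveolar markers allow would bring at most 5.05% of the gain of Spp1 (0.167% for Arg1). More classical monocytes, the exposure and the sea level preparation stay open. The monocyte list had camera adjusted p = 0.0961 (0.0374 without day 4 replicate 1). Its level was 5.14, 5.76 and 6.58 at day 4 (Arg1 high in each) and 4.09 to 5.59 at sea level.

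The 6 libraries of each comparison with 3 against 3 give 10 splits, too few for a share under 0.05. In alveolar macrophages at day 14 against day 4 the real split gave 2 genes and the highest other split 4, with 8 splits reaching the real count, but at an unadjusted p below 0.05 limma gave 1822 in the real split and 487 to 812 in the others. In interstitial macrophages at day 4 against sea level the real split gave 1460 and the highest other 2 (3773 and at most 624 by limma at an unadjusted p below 0.05), at day 14 against sea level 1083 and 0 (3434 and at most 935), and at day 14 against day 4 13 and 5 (2165 and at most 567), each with 1 split, the real one, reaching the count.

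The results that follow are differences between the cell types in the change from sea level (the effect). They come from the limma or camera test of that difference (interstitial minus alveolar). An effect of altitude on them cannot be told apart from library type, since the small RNA share at sea level was 44.1 to 47.2% in alveolar and 54.5 to 59.6% in interstitial libraries. At day 4 there were 208 genes. The largest higher interstitial effects included Arg1 (4.30), Spp1 (4.27), Il1rn (2.38), Gclm (2.32), Arg2 (1.75), Ube4b (1.71), Gyk (1.65), Ccr1 (1.64) and Amica1 (1.64). The 10 largest lower ones were in Gpx3 (-5.30), Pla2g2d (-4.00), Ccl17 (-3.21), Chp2 (-2.92), Scamp4 (-2.89), Cbr2 (-2.55), Rplp1 (-2.38), Selo (-2.34), Gal (-2.32) and Ccdc107 (-2.26). Among lists, cell cycle (camera adjusted p = 0.0064) and interferon-stimulated genes (0.015) had a higher interstitial effect. MHC class II (0.034), cholesterol biosynthesis (2.44e-11), heat shock (0.0064), iron and heme (0.0132), T and NK cells (0.00387), alveolar epithelium (0.0143), dendritic cells (0.0289), endothelium (0.00651), fibroblasts (0.00387), interstitial macrophages (2.9e-07), neutrophils (0.0289), nonclassical monocytes (0.0448), oxidative phosphorylation (0.0292) and ribosomal proteins (9.12e-08) had a lower one. With an estimated correlation these lists had adjusted p between 0.336 and 0.822. Without some 1 library or under another setting of the camera test, all but the cholesterol, T and NK cell, interstitial macrophage and ribosomal lists lost their call.

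At day 14 the test of the difference called 596 genes. The higher interstitial effects were in Spp1 (2.03), Ccdc146 (1.73), Gclm (1.62), Mybl1 (1.52), Gcc2 (1.43), Smarca5 (1.38), Chil4 (1.37), Ergic2 (1.31), Pkd2l2 (1.23) and Slc7a2 (1.21), and the lower ones in Prg4 (-4.90), Slpi (-4.33), Alox15 (-3.84), Ptgs2 (-3.29), Ccl17 (-3.26), Selp (-3.24), Retnla (-3.13), Serpinb2 (-3.11), Crip1 (-3.02) and Scamp4 (-3.02). Club and ciliated cell (camera adjusted p = 0.0442), endothelial (0.0162) and fibroblast markers (0.000668) had a higher interstitial effect. A lower one was found for MHC class II (3.35e-06), cell cycle (0.0296), chemokine receptors (0.00231), cholesterol biosynthesis (1.98e-05), complement (0.00384), glycolysis (0.00325), heat shock (0.00474), inflammatory cytokines (1.07e-07), interferon-stimulated genes (0.000629), iron and heme (0.0296), lipid uptake (0.00503), lysosome (0.000241), T and NK cells (0.00536), classical monocytes (0.000153), interstitial macrophages (4.87e-10), neutrophils (0.0024), nonclassical monocytes (0.000194), oxidative phosphorylation (9.61e-08) and ribosomal proteins (4.61e-13). With an estimated correlation their adjusted p lay between 0.0886 and 0.658. At the preset correlation, the club, endothelial, cell cycle, glycolysis, iron and lysosome lists lost their call without some 1 library or under another setting.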

How the results depend on the processing

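Of the tests in this part, those with the length and GC trend removed, with the restricted gene set, with both, with the 2 hypoxia groups alone and with the block across cell types were chosen after the results were seen, and the others were planned. Over named genes and settings, the side of the threshold held in 15431 cases. A call was lost in 1447 and gained in 307, and signs reversed, called or not, in 11. Lists kept their call in 1201 and lost it in 298. Reversed values in alveolar macrophages at day 14 were, with the length and GC trend removed, Hmox1 (-0.097), Gsr (-0.050), Tppp3 (-0.31), Naaa (-0.25), Batf3 (-0.21), G0s2 (-0.056) and Ear2 (-0.14), with the restricted set as well Naaa (-0.14) and Batf3 (-0.15), and with median centring Naaa (-0.064). In interstitial macrophages at day 14 H2-Aa was 1.43 with quantile normalization. The removed trend accounts for the reversals under that setting, and the cause of the others was not tested. With a pseudocount of 0.1 median differences of several lists of low genes grew by over 1.5 times, for example T and NK cells in interstitial macrophages to -2.25 and -1.93 at day 4 and 14. Correlations of day 4 and day 14 effects were 0.967 and 0.864 with pseudocount 0.1, against 0.971 and 0.849.

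In alveolar macrophages at day 4 (5054 genes), the count was 3284 with a mean of at least 5 FPKM, 2814 in the restricted set and 2165 with the trend also removed, and at day 14 (6514) it was 4156, 3946 and 2928, settings that test fewer genes. The authors' deposited q-values below 0.05 numbered 2472 and 3054, of which 2430 and 3031 are among these genes. In interstitial macrophages at day 4 (1460) the count was 881 without the filter, 2316 in the joint fit, 350 in the restricted set and 295 with the trend also removed, and at day 14 (1083) it was 550 without the filter, 195 and 191. The difference between cell types at day 4 (208) was 15 in the restricted set and 1 with both, and at day 14 (596) it was 307 with median centring, 299 with quantile normalization, 248 with the trend removed, 224 in the restricted set and 14 with both. Alveolar macrophages at day 14 against day 4 (2) gave 5 with pseudocount 0.1 and, by limma, 0 in the restricted set and 0 with both (1213 and 867 at an unadjusted p below 0.05), and interstitial macrophages (13) gave 26 with both and 44 with the 2 groups alone. Apart from the smaller number of genes tested, the cause was not tested. With any 1 library left out the counts in this order of comparisons ranged from 1835 to 5614, 3911 to 6090, 517 to 1641, 361 to 1531, 4 to 656, 6 to 1799, 0 to 9 and 3 to 66, the 0 being limma without day 4 replicate 1 (1752 at an unadjusted p below 0.05).

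Lists past the threshold numbered 10, 10, 6, 11, 16, 22, 8 and 13 in the same order. With an estimated correlation camera called 0 in each, with 0, 0, 2, 1, 2, 9, 2 and 5 at an unadjusted p below 0.05. By fry, which does not compare a list with other genes, there were 23 and 31 in alveolar macrophages, 4 in interstitial macrophages at day 14, 8 for the difference at day 4, and 0 (6 unadjusted) and 5 for day 14 against day 4. In the restricted set alveolar macrophages had 3 and 5 lists, with the trend also removed 3 and 6. At day 14 against day 4 they had 5 with median centring and 5 with the trend removed, and the cause was not tested. With any 1 library left out the numbers ranged from 4 to 13, 9 to 13, 6 to 11, 8 to 11, 10 to 17, 20 to 22, 5 to 13 and 11 to 16.

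The labels number the samples of all groups, but the deposited sea level columns carry only letters. With the replicate number as a block, limma called 0 genes (1701 at an unadjusted p below 0.05) in alveolar and 2 in interstitial macrophages at day 14 against day 4. Deviations of same-numbered samples correlated at 0.0222, -0.0166 and -0.000676 in alveolar and -0.0424, 0.0181 and -0.00848 in interstitial macrophages, which gives no sign that the number pairs the samples. Between the cell types same-numbered samples correlated at 0.234, 0.00866 and 0.0882 at day 4 and 0.0516, -0.00705 and 0.041 at day 14, and 3 of the 6 alveolar samples (replicate 1 at day 4, 1 and 3 at day 14) correlated best with their own number, so pairing across cell types stays open. With the number of the hypoxia libraries as a replicate block across cell types, their difference had 160 calls at day 4 and 225 at day 14. No paired analysis was possible because the sea level columns carry only letters, which holds for each comparison with sea level and for their part in the differences between cell types. Separate parts of the sea level libraries could not be formed for the overlap because 2 or 3 libraries do not give parts of at least 2.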

Other observations

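The list and gene tests in this part were planned, and the values of single libraries and of transcript length classes were chosen after they were seen.

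In alveolar macrophages at day 14, genes of the lysosome were mostly higher than at sea level (20 of 29 rose, 3 fell, 6 not called; 21 and 3 adjusted over the list alone), though the list did not pass (camera adjusted p = 0.0551, and 0.606 with an estimated correlation). Psap, the precursor of the saposins that help degrade sphingolipids, rose from 88.9 ± 6.15 to 276 ± 20.9 FPKM, by 1.62 ± 0.10 (limma adjusted p = 0.000117). The sea level preparation cannot be told apart from the exposure here.

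Replicate 1 of interstitial macrophages at day 4 stood apart from replicates 2 and 3. Prg4 was at 770.4, 6.64 and 39.9 FPKM in the 3 libraries in order, Alox15 at 345, 4.07 and 35.1, Slpi at 429, 7.40 and 30.2, and Selp at 55.7, 0.212 and 2.75. The opposite order held for Ly6c2, a monocyte antigen, at 1.64, 52.5 and 94.7 and the interferon-stimulated gene Isg15 at 1.44, 13.4 and 22.9.

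Short transcripts had the higher differences from sea level. Median differences in alveolar macrophages at day 4 were 1.09 for longest transcripts under 1000 bases, 0.633 and 0.27 in the next 2 classes, each to double the length, and -0.00253 for longer ones. At day 14 they were 1.29, 0.748, 0.373 and 0.0882, with ribosomal protein genes left out. In interstitial macrophages they were 0.486, 0.251, 0.124 and -0.0164 at day 4 and 0.372, 0.241, 0.113 and 0.0735 at day 14. At day 14 against day 4 alveolar macrophages had 0.209, 0.136, 0.101 and 0.092, and interstitial macrophages had the opposite order, at -0.169, -0.0674, -0.0319 and 0.038.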
